A study of Mus musculus with 28 samples.

How the data were processed

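Midbrain RNA of mice injected with 1000000 CT-26.WT cells in 300 µl PBS or with PBS alone, at 8 weeks of age, was hybridised to in-house printed oligonucleotide arrays, per the labels. RNA was either total RNA (7 biological replicates, each on arrays of both dye orientations) or polyA RNA (6 biological replicates, mostly in 1 orientation). Nothing in the labels says whether a biological replicate was 1 animal or a pool. The deposited scanner files give spot intensity values for the Cy3 and Cy5 channels with the local background already subtracted, per the file headers; the scanning software is not given in the sources used here. Each array has several scans. The deposited series matrix was read as log2 ratios of tumour over PBS made by the authors by a method not given in the sources used here: column medians lie between -0.013 and 0.012, signs follow the dyes of the labels, and values correlate with the scanner ratios at 0.546 to 0.911. Whether its base is 2 or e stayed unknown, and it was used only as an alternative.

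Gene names came from the platform annotation. Of 9008 accessions, 4855 were named through the accession and 4057 through the gene number in a reference table, 85 kept the platform's symbol and 11 had several symbols and were not named. About 994 to 1002 of the 10080 spots on each array are unnamed here. The annotation was checked by spot brightness, a check chosen after the data were seen. On 3 of the 5 array designs the brightness by gene followed that of the other designs (Spearman rho 0.548 to 0.682, across genes) and ribosomal protein genes lay at mean percentiles of 81.0 to 85.0. On the other 2 designs rho was 0.057 and 0.186 and ribosomal genes lay at 49.9 and 45.5. No reordering of the grid, out of 1920 combinations of order and annotation for each design, gave a rho above 0.090 and 0.158. For the latter design, 0.158 was the rho of the order as deposited. The 7 arrays of these designs, 6 at 72 h and 1 at 192 h, were therefore left out of the comparisons of named genes. This departs from the plan of using all 28 arrays: 72 h keeps 2 replicates, and a probe needed a value in 2 replicates there in place of 3. The result with all 28 arrays is among the alternatives.

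In R 4.3.3 with limma 3.58.1, log2 ratios of Cy5 over Cy3 were loess-normalized within each scan (span 0.3, 4 iterations). All spots with a signal in both channels entered the curve, since no control spots are marked. Scans and spots of one accession were averaged, signs were turned to tumour over PBS by the labels' dyes, and arrays of one biological replicate were averaged. The dimmest 33.3% of probes were left out, and a probe needed values in 3 replicates at 18 and 192 h, which left 4663 probes for 4570 genes; 2299 probes had a value in every replicate. A linear model with a mean for each time and a dye term was fitted by limma's method over all replicates, with 7 residual and 4.64 prior degrees of freedom, and Benjamini-Hochberg adjustment at 0.05. Least squares were solved exactly for each pattern of missing values, which gave limma's p-values for the single times. Because spots are missing on some arrays, a probe of a balanced replicate can rest on 1 dye orientation. Arrays carry no counts, and the number of replicates limits the precision; the median SE was 0.12 at 18 h, 0.18 at 72 h and 0.13 at 192 h. The labels say biological replicates, and p-values measure the spread between them, pooled over the 3 times.

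The 32 gene lists were fixed before any value was seen, and the 22 with at least 5 measured genes were tested with camera (preset correlation 0.01, and an estimated one) and, on genes with complete values, fry. Genes named in the text follow a rule fixed at the same time: per time, 20 genes of one sign in every replicate, filled by smallest p where none passed, of which the 8 with the smallest p are given; 10 each for the mean and the F-test, given in part; and at most 2 of each list by moderated t. Nr1d2, Ndufb11, Ndufb3, C1qb, Isg15 and Oxt fall outside the rule and were chosen after their values were seen. Where a named gene had several probes, that with the smallest p was used; the list tests, and the values of those 6 genes, rest on the probes of a gene averaged.

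The fit was tested on simulated data with the real missing values and the fitted spread of each probe, 200 of 4663 probes changed and 10 simulations. Of changes of 1 on the log2 scale it recovered 97.2% at 18 h, 88.2% at 72 h and 97.0% at 192 h. Of changes of 0.5 it recovered 48.9%, 0.15% and 36.7%. The oxidative phosphorylation list, with 44 genes, was shifted by 0.2 and tested for the mean of the times. It was called in 10 of 10 simulations over 4570 genes, and 2 lists were called in the 10 simulations without a shift. The noise of these list simulations was the residual spread of each gene, not corrected for the fitted terms, and held no dye effect. Shifts under 0.2, of smaller lists or at single times were not simulated. The list's real mean over the times was 0.04, a size the simulation says nothing about. The simulated noise was independent between probes and arrays, unlike the arrays here, which correlate by dye orientation. That noise had the same spread in every replicate. The real SD across probes ran from 0.19 in 192 h replicate 3 to 0.67 in 72 h replicate 3. Balanced replicates were given no dye effect, also where a probe rests on 1 orientation. The shares recovered hold only for such noise. Alternatives covered background, normalization, scans, filters, spot flags, the dye term, RNA type, replicate blocks, array weights, variance model, gene averages, series matrix values and each replicate left out; 4 more were added after the data were seen. Background subtraction was already in the deposited values.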

Results

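Gene expression in the midbrain of male BALB/c mice was compared between animals carrying a subcutaneous injection of CT-26.WT cells, a mouse colon carcinoma line, and animals injected with PBS alone. The series asks how the midbrain responds at 18, 72 and 192 h after the injection. Each array held midbrain RNA of both conditions, 1 in Cy3 and the other in Cy5, so each spot gives a ratio of tumour-bearing over PBS mice. The labels give 28 arrays from 13 biological replicates, 5 at 18 h, 4 at 72 h and 4 at 192 h. Named genes could be read from 21 arrays, covering 11 replicates: 5 at 18 h, 2 at 72 h and 4 at 192 h. On these arrays a median of 69.0% of the spots had a signal in both channels, from 25.7% to 97.9%. Values below are log2 ratios of tumour over PBS, given with the standard error (SE) of the fit and the number of replicates with a value (n).

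The correlation between arrays went with the orientation of the dyes. Arrays with the same dye orientation had a mean Pearson r of 0.237 across probes in 102 pairs, and arrays of opposite orientation a mean r of -0.231 in 108 pairs. Within 1 biological replicate, the 7 pairs of opposite orientation had a mean r of -0.341, and only 1 of them lay above 0. The 4 pairs of the same replicate and orientation had a mean r of 0.434. Probes are not independent replicates, so these correlations carry no p-value.

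**Figure D1:**
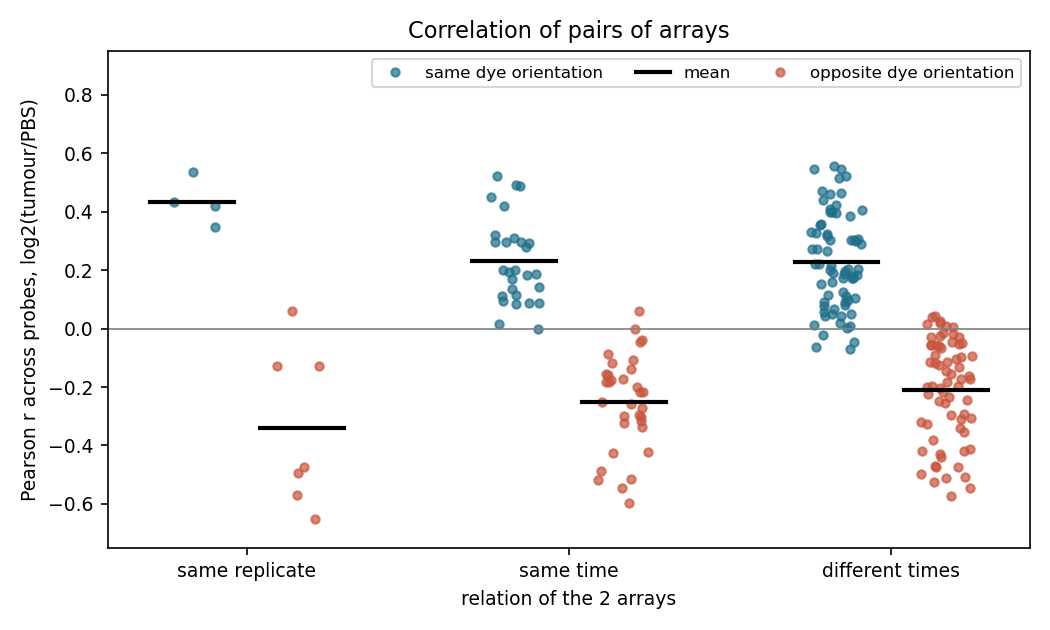
Pearson correlation across probes (vertical axis) of the log2 ratios of tumour over PBS between pairs of arrays, grouped by whether the arrays share a replicate, a time or neither (horizontal axis); each point is a pair, colours give the dye orientation and black bars the mean. Pairs of opposite orientation average -0.341 within a replicate, below 0 as in the other groups.

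At 18 h the gene with the smallest p among those of one sign in every replicate was Tpp2, which encodes tripeptidyl peptidase II, with a log2 ratio of 0.46 (SE 0.12, n = 5). Taf1b, a subunit of an RNA polymerase I initiation factor, had 0.57 (SE 0.15, n = 4), and the phosphatase subunit Ppp2r2b had 0.53 (SE 0.15, n = 4), with another probe of that gene of opposite sign. Negative values were measured for Mkrn2, at -0.50 (SE 0.13, n = 4), and for the cytosolic nucleotidase Nt5c2, at -0.39 (SE 0.11, n = 5). Entpd8 had 0.47, Olfr893 had 0.39 and Prrg2 had 0.35. None of these genes passed the test: limma called 0 of 4663 probes at an adjusted p under 0.05, with a lowest adjusted p of 0.878. At an unadjusted p under 0.05 there were 250 probes, 128 higher and 122 lower. The median 95% confidence interval at 18 h was 0.27 wide on each side, without adjustment for the 4663 probes. In the simulated data, tested with adjustment, 48.9% of changes of 0.5 were recovered at 18 h. Changes of that size and below could therefore be missed.

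At 72 h the largest ratios among the genes with the smallest p belonged to Sfrp5, a secreted antagonist of Wnt signalling, at 4.67 (SE 0.86, n = 2), and Brd8, a bromodomain protein, at 3.62 (SE 0.55, n = 2). Rbm33 had 3.25 (SE 0.51, n = 2) and the sulfotransferase gene Chst13 had 2.81 (SE 0.40, n = 2). These SEs rest on a spread pooled over the 3 times, not on the 2 replicates alone. Replicates 3 and 4 gave 7.22 and 2.12 for Sfrp5 and 5.19 and 2.05 for Brd8. They gave 4.44 and 2.06 for Rbm33 and 3.00 and 2.61 for Chst13. Cct5, a subunit of the cytosolic chaperonin, had 0.82 (SE 0.15, n = 2). The kinase gene Map3k4 stood at -0.84, Rnf187 at -0.66 and Pcp4l1 at -0.64. None passed: limma called 0 of 4663 probes, with a lowest adjusted p of 0.093 for Chst13 and Rbm33, and 409 probes had an unadjusted p under 0.05. Rbm33, Brd8 and Sfrp5 had values only on arrays with the tumour sample in Cy3, in both replicates. In replicate 4, Chst13 and Cct5 also had a value only with the tumour in Cy3, and Map3k4 and Rnf187 only with it in Cy5. Chst13 gave 6.23 on the replicate 3 array with tumour in Cy3 and -0.23 on its partner with the dyes exchanged. Cct5 gave 2.00 and -0.01 on the same 2 arrays, and Map3k4 -1.70 and -0.15. That Cy3 array, array 447, had a correlation of 0.077 between its channels. Its Cy5 channel, which held the PBS sample, followed the other arrays at a Spearman rho of 0.050. On the other 20 arrays used, the Cy5 channel lay between 0.339 and 0.807, and on the 7 arrays left out between 0.024 and 0.184. Array 447 was kept in the main fit, and without it 188 probes had an unadjusted p under 0.05. Without it Chst13 had a fitted 2.33 (plain replicate mean 1.19), Cct5 0.40 (0.31), Map3k4 -0.47 (-0.45) and Rnf187 -0.66 (-0.51), none passing, and the other 4 genes had too few values to be tested. At the other times, polyA replicates 1 (tumour in Cy5) and 2 (tumour in Cy3) had opposite signs for these genes. Rbm33 gave -1.92 and 2.08 at 18 h and -3.09 and 3.50 at 192 h. Sfrp5 gave -1.66 and 3.10 at 18 h, and Brd8 -2.80 and 3.40 at 192 h. The 72 h values of these 3 genes have the sign seen there with the tumour in Cy3.

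At 192 h the largest absolute value among the genes with the smallest p belonged to Gja10, a connexin of gap junctions, at -2.06 (SE 0.45, n = 3), where the plain replicate mean was -2.38. Replicates 1, 3 and 4 gave -2.77, -0.89 and -3.47. Replicate 1 had the tumour only in Cy5, and replicate 2, with the tumour only in Cy3, had no value. At 18 h replicate 2, also with the tumour only in Cy3, gave 1.59, and replicates 4 and 5 gave 0.23 and 0.39. Fnbp4 had 0.50 (SE 0.14, n = 4), the transcript 4930524B15Rik had 0.39 (SE 0.11, n = 4), and Idh2, the mitochondrial isocitrate dehydrogenase, had 0.40 (SE 0.13, n = 4). Atf3, a stress-responsive transcription factor, had 0.33 (SE 0.11, n = 4), above 0 in all 4 replicates, as the rule for these genes required one sign. Mpv17l had 0.32, while Slc3a1 stood at -0.32 and the Notch-regulated gene Nrarp at -0.36. None passed: limma called 0 of 4663 probes, with a lowest adjusted p of 1.00, and 46 probes had an unadjusted p under 0.05, 23 in each direction. That count is below the share of 0.05 of the probes that no effect at all would give.

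**Figure D2:**
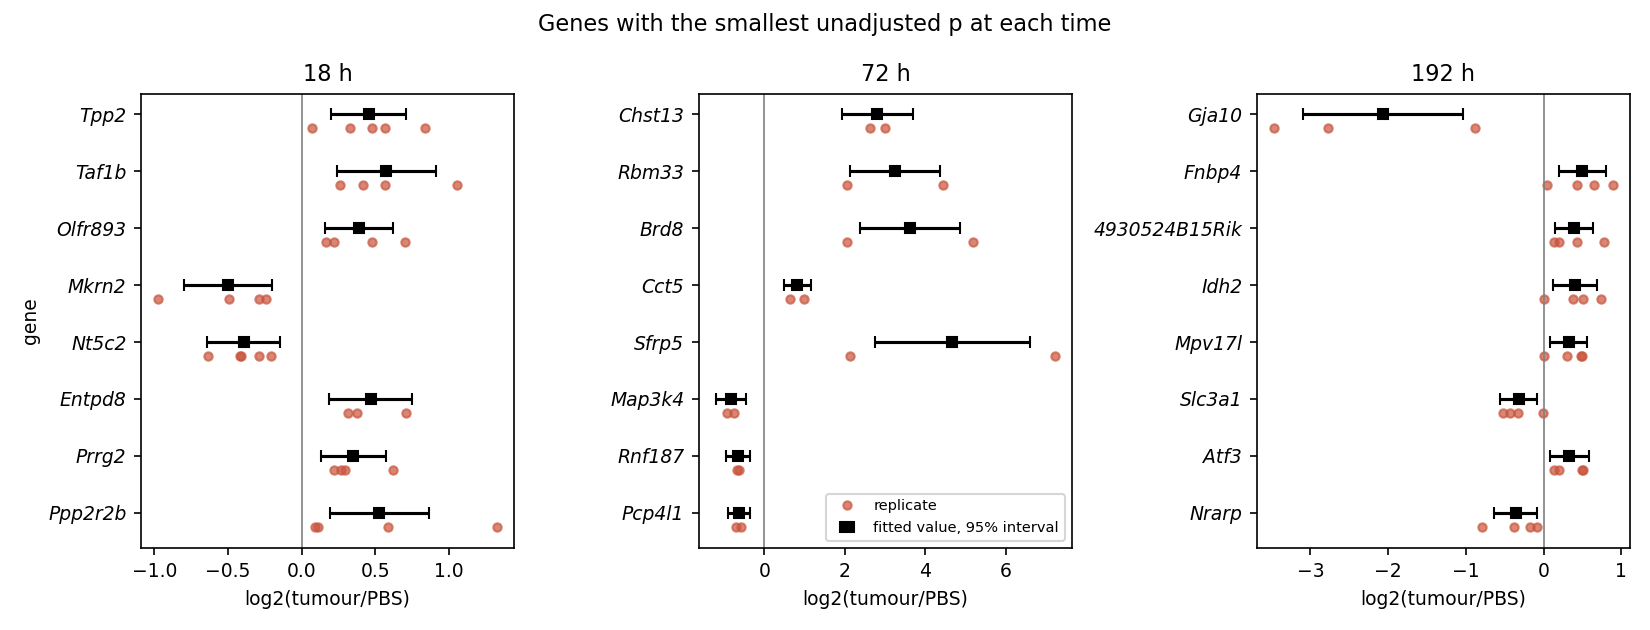
Log2 ratio of tumour over PBS (horizontal axes) for the 8 genes (vertical axes) with the smallest unadjusted p and one sign in every replicate at each time; squares are fitted values with 95% confidence intervals and circles the biological replicates. The intervals are not adjusted for 4663 probes, none of the genes passed the test, and the 72 h axis reaches beyond 6 because of Sfrp5.

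Averaged over the 3 times, the smallest p values belonged to the 72 h genes Chst13, with a mean log2 ratio of 1.06 (SE 0.19), Rbm33, at 1.16 (SE 0.23), and Rnf187, at -0.29 (SE 0.06). Brd8 had 1.38 (SE 0.28) and Rprd2 had -0.48. limma called 0 probes for the mean, with a lowest adjusted p of 0.610 and 262 probes at an unadjusted p under 0.05. The F-test between times had its smallest p values for 3 of these genes: 192 h minus 72 h gave -2.91 for Chst13, -3.22 for Rbm33 and -3.55 for Brd8. It called 0 probes, with a lowest adjusted p of 0.905 and 167 probes at an unadjusted p under 0.05. At 192 h, replicates 1 (tumour in Cy5) and 2 (tumour in Cy3) gave -1.54 and 1.89 for Chst13. They gave -3.09 and 3.50 for Rbm33 and -2.80 and 3.40 for Brd8. At 72 h Rbm33 and Brd8 had values only with the tumour in Cy3, so orientation and time cannot be told apart for them. Between pairs of times limma also called 0 probes, with 290 at an unadjusted p under 0.05 for 72 h minus 18 h, 105 for 192 h minus 18 h and 278 for 192 h minus 72 h.

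Among the gene lists, the circadian clock list had the lowest p at 18 h: its 6 genes had a mean log2 ratio of -0.14, with 3 above 0 (camera adjusted p = 0.209). Clock, a core circadian transcription factor, had -0.37 (SE 0.11, n = 5), above 0 in 1 replicate, Cry2, a repressor of the clock, had -0.44 (SE 0.16, n = 5), above 0 in 2 replicates and at -1.72 in replicate 2, and the nuclear receptor Nr1d2 had -0.21 (SE 0.08, n = 5). These 3 passed when adjusted over the list alone, and 0 of the 6 passed over all genes. Camera called 0 of 22 lists at each time and for the mean of the times, also with an estimated correlation. The numbers of lists at an unadjusted p under 0.05 were 2, 2, 1 and 1, and fry called 0 of the 11 lists it could test.

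None of the lists for the cell types of the midbrain passed the test. List means here are means of fitted values, and genes at 72 h have n = 2, with the values of replicate 3, which holds array 447, and replicate 4 in brackets. The 11 dopaminergic genes had mean log2 ratios of -0.06 at 18 h, 0.08 at 72 h and 0.04 at 192 h; among them Pitx3 had 0.56 at 72 h (0.96 and 0.17) and Nr4a2 0.48 at 18 h (SE 0.16, n = 4), where the list median was -0.18. Fitted means at the same times were 0.00, 0.01 and 0.12 for the GABAergic list, whose plain replicate mean at 192 h was 0.02; its Gabrb2 had a fitted value of 0.55 there against a plain mean of 0.11. The glutamatergic list, with Grin2a at 0.36 at 72 h (0.56 and 0.16) and Grin2b at -0.26 at 18 h, had means of -0.06, 0.23 and 0.00. Those of the neuropeptide list, with Tac1 at 0.27 at 72 h (0.44 and 0.11), were 0.06, 0.01 and 0.05. The synaptic vesicle list, which holds Stx1a at -0.73 at 72 h (-1.09 and -0.36) and Sv2a at 0.59 at 18 h (1.76 in replicate 5), had 0.04, -0.10 and -0.06. For astrocytes, with S100b at 0.33 at 72 h (0.48 and 0.17), the means were -0.03, 0.16 and 0.01, and for oligodendrocytes, with Mal at 0.37 at 72 h (0.82 and -0.08), 0.04, 0.19 and -0.08. The myelin gene Pllp, at 1.25 at 72 h (2.62 and -0.12) and -0.66 at 192 h, weighs on the means at these times, where the list medians were 0.01 and 0.00. The lymphocyte list had 0.07, -0.24 and 0.05, with Gzma at 0.44 at 18 h, above 0 in 3 of 5 replicates, and Cd79a at -0.48 at 72 h (-0.74 and -0.22), and the cerebellar list, with Cbln3 at -0.35 at 18 h, below 0 in 3 of 4, had -0.10, -0.01 and -0.03. Plain replicate means at 18 h were 0.14 for lymphocytes, -0.05 for the cerebellar list, 0.05 for the GABAergic list and 0.20 for olfactory receptors. Ion channels had -0.03, 0.07 and 0.04, with Kcng4 at 1.49 (2.68 and 0.31) and Scn1a at -0.95 (-1.66 and -0.23) at 72 h, and olfactory receptors, not expected in midbrain, had 0.11, 0.17 and -0.16, with a median of 0.00 at 192 h.

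None of the lists for inflammation, stress and metabolism passed either. The inflammatory cytokine and NF-kB list had mean log2 ratios of -0.09, -0.03 and 0.02 at 18, 72 and 192 h, with Vcam1, an adhesion molecule, at -0.29 (SE 0.12, n = 4) at 18 h. Cebpd, also in the glucocorticoid-responsive list, had 0.25 (SE 0.10, n = 4) at 192 h, above 0 in 4 of 4 replicates. Glucocorticoid-responsive genes had means of -0.01, -0.06 and 0.06, immediate early genes 0.04, 0.10 and 0.05, and heat shock genes 0.03, -0.03 and -0.05, with Hsph1 at -0.15 at 192 h. The antioxidant list, with Txn1 at 0.50 (0.94 and 0.06) and Gstm5 at 0.49 (0.96 and 0.01) at 72 h, had 0.03, 0.08 and 0.05. Lipid synthesis, with Sqle at 0.32 at 18 h and Scd2 at 0.69 at 72 h (1.40 and -0.02), had 0.05, 0.09 and -0.03, and apoptosis, with Casp2 at 0.29 and Pmaip1 at -0.82 (-2.02 in replicate 5, n = 3) at 18 h, -0.13, -0.08 and 0.05. The proteasome list, with Psmd7 at -0.69 at 72 h (-1.42 and 0.05), had -0.03, -0.02 and -0.02, and ribosomal proteins, with Rpl27 at 0.19 (0.71 in replicate 1) and 1 probe of Rpl11 at 1.01 (2.93 in replicate 2, n = 3) at 18 h, 0.00, 0.04 and -0.02. A further 10 lists had under 5 measured genes and were not tested; in them C1qb, a complement gene of microglia, had 0.01 at 18 h, the interferon gene Isg15 had -0.10, and Oxt, which encodes oxytocin, had -0.39 (SE 0.13, n = 5), above 0 in 1 replicate.

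**Figure D3:**
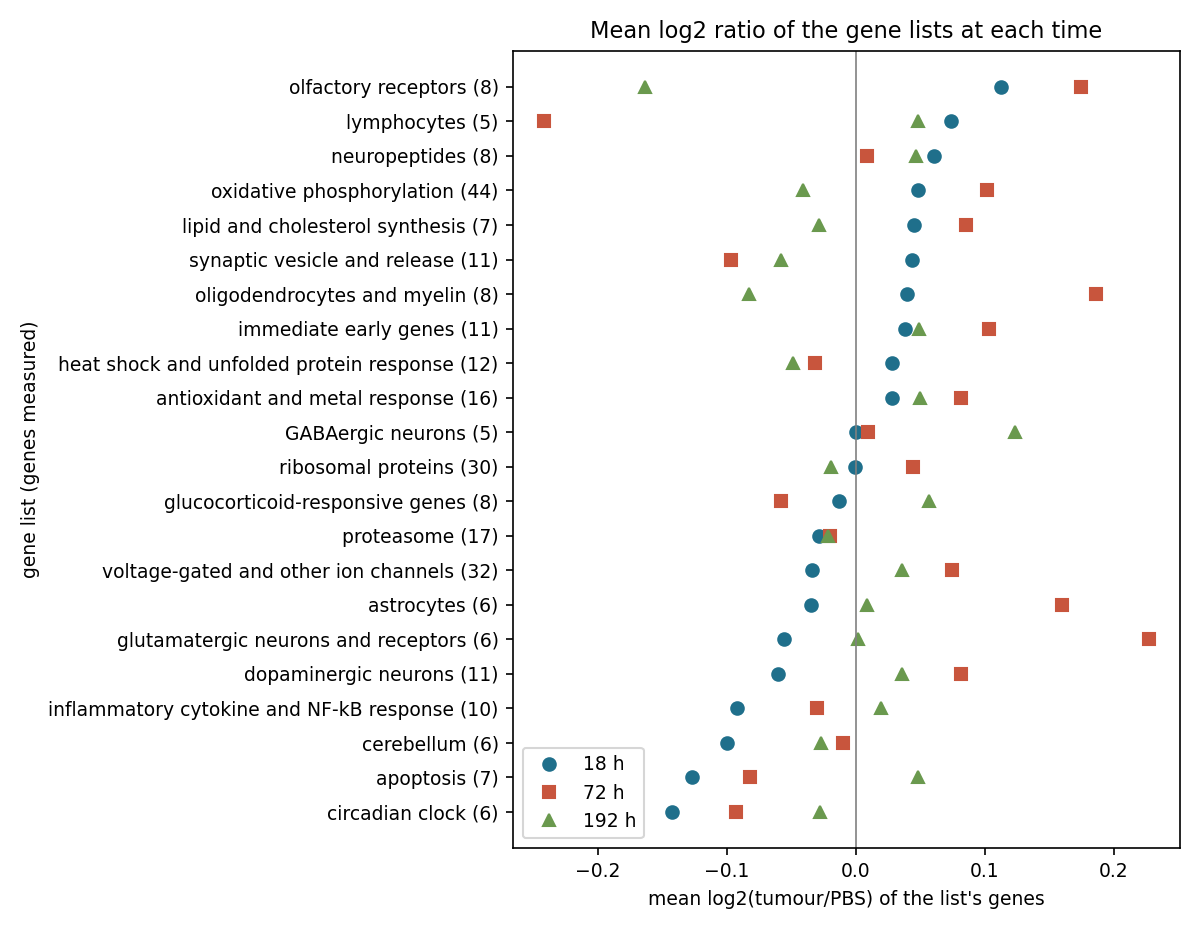
Mean fitted log2 ratio of tumour over PBS of the genes in each list (horizontal axis) for the 22 lists with at least 5 measured genes (vertical axis, number of genes in brackets); symbols give the time. All means lie between -0.24 for lymphocytes and 0.23 for the glutamatergic list, both at 72 h, and none of the lists passed camera's test.

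The oxidative phosphorylation list, which holds subunits of the mitochondrial respiratory chain, had a mean log2 ratio of 0.05 at 18 h, 0.10 at 72 h and -0.04 at 192 h over 44 genes. At 18 h Ndufb11 had 0.21 (SE 0.08, n = 5) and Ndufb3 had 0.26 (SE 0.12, n = 5), both above 0 in all 5 replicates, while at 72 h Cox8a had 0.50 (0.72 in replicate 3 and 0.28 in replicate 4) and Ndufb10 had 0.50 (0.92 and 0.07). In a follow-up test between times, 192 h minus 18 h gave -0.09, and 13 of the 44 genes lay above 0. Camera's adjusted p was 0.033 over the 22 lists of that contrast, 0.027 with an estimated correlation, but 0.099 over all 66 list tests between times. For 192 h minus 72 h the same list had -0.14 with an adjusted p of 0.104, which became 0.0095 without array 447, 0.010 without background correction and 0.047 with dim probes kept. The list tests between times were not planned and were added after the data were seen. Replicate means were above 0 in 4 of 5 replicates at 18 h and in 1 of 4 at 192 h, and the total RNA replicates alone gave -0.064 with an adjusted p of 0.669.

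**Figure D4:**
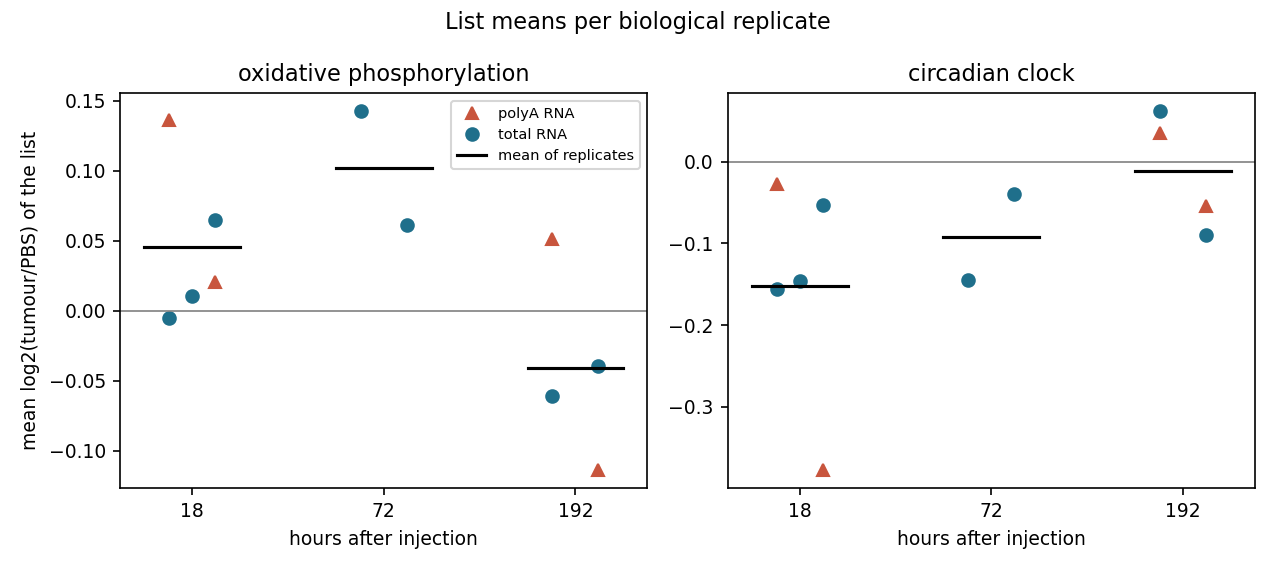
Mean log2 ratio of tumour over PBS (vertical axes) of the oxidative phosphorylation and circadian clock lists in each biological replicate by hours after injection (horizontal axes); triangles are polyA RNA, circles total RNA and bars the mean of the replicates. The oxidative phosphorylation means are 0.05 at 18 h and -0.04 at 192 h, with overlapping replicates.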

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

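The tests on the array correlations, the sign changes of replicates, the part carried by dye orientation and the single arrays left out at 72 h were chosen after the results were seen; the other predictions on the 72 h ratios and on oxidative phosphorylation were written before their tests were run, but the patterns themselves were picked from the results. Among 89 groups of replicates or arrays checked for a value far from the others, 4 stood apart, against 4.45 that chance gives at 1 in 20. Rpl27 had a log2 ratio of 0.71 in 18 h replicate 1, with the others between -0.03 and 0.14. The astrocyte list had a mean of -0.51 in 18 h replicate 3, with the others between 0.02 and 0.23. The GABAergic list had -0.18 in 192 h replicate 2, with the others between 0.08 and 0.10. The channels of array 447, of 72 h replicate 3, correlated at a Spearman rho of 0.077, where the other 3 arrays of 72 h used for named genes lay between 0.882 and 0.943.

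Dye orientation went with the correlation of arrays. Ratios of Cy5 over Cy3, not turned by condition, correlated at a mean r of 0.231 over 108 pairs of opposite orientation; this is the observed correlation with its sign turned, so it tests nothing about a dye effect of each probe. limma's dye term passed for 31 of 4663 probes, with 611 at an unadjusted p under 0.05, but it rests on the polyA replicates, where orientation goes with the replicate number. If the dyes of the labels are right, the mean r of -0.341 over 7 pairs argues against a tumour effect shared by both orientations of a replicate as the main source of the ratios. Of 102 pairs of the same orientation 97 lay above 0, and of 108 pairs of opposite orientation 9 did. Wrong dye labels on only a few arrays would mix these signs, so this argues against them as the source of the pattern. Wrong labels on nearly every array of the same orientation were not tested and cannot be told apart from a dye effect of each probe. With such labels a tumour effect would stay open, and a smaller tumour effect stays open in any case.

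At 72 h, 79 probes had an absolute log2 ratio over 1, and without array 447 there were 53, but 24 of these were other probes: of the 79, 18 had too few values left and 29 of the remaining 61 stayed over 1. With the other 72 h arrays left out 1 at a time, 44 of 47, 61 of 69 and 57 of 59 stayed. By the rule of that test, the 29 count against the Cy5 channel of array 447 as their only source. But without that array replicate 3 keeps 1 orientation, and its fitted values lean on the dye term of the polyA replicates. Chst13, for instance, had a fitted 2.33 against a plain replicate mean of 1.19. The source therefore stayed open for the 29, as for the 32 that fell below 1 and the 18 untested. For the 230 probes over 1 in replicate 3, the median in replicate 4, signed as in replicate 3, was 0.0033, and 50.9% had the same sign. These probes were picked in replicate 3, which holds array 447 and had an SD across probes of 0.67. Replicate 4 had an SD of 0.24 and 33 probes over 1. With the dyes of the labels, the median argues against a tumour effect shared by both replicates as the main source of these picked ratios. Because of the pick it says nothing about a shared tumour effect on other probes. A difference between the replicates stays open and untested.

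The oxidative phosphorylation list differed between 18 h and 192 h by -0.089 in a test of the difference itself. Its mean difference lay at percentile 4.18 of 10000 random lists matched on brightness, whose median was -0.04. By the limits set beforehand, this did not set the list apart from lists of like brightness. Since their median was smaller in size, brightness may carry a part of the difference rather than the whole. The orientation of the arrays with a value carried -0.0019 of the difference. Orientations nearly cancelled at both times, so a small part was set in advance by the design. With the total RNA replicates alone the difference was -0.064. By the limits set beforehand, that did not decide whether the unbalanced polyA replicates gave rise to it. Of the 126 splits of the 9 replicates, 9 gave a difference of list means as large as the real -0.09, the highest other being 0.11 in size, so chance could not be excluded. A change of respiratory chain transcripts with time remains a hypothesis these tests do not favour.

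Turning the signs of replicates gives a measure of chance for the counts at an unadjusted p under 0.05. At 18 h the real count was 250 and the highest of the other 15 sign patterns gave 435, with 8 of 16 as large; 16 patterns are too few for a share under 0.05. At 192 h the real count was 46 and the other patterns gave 51 to 178, with 8 of 8 as large, again too few patterns. Without any effect, a share of 0.05 of the 4663 probes would lie under 0.05. The count at 192 h was well below that share, and those at 18 h and for the mean were near it. For the mean of the times, 36 of 100 patterns drawn from 1024 gave at least the real 262, the highest other being 430, so chance could not be excluded.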

How the results depend on the processing

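Of the alternatives below, those with all 28 arrays, without array 447, with values in both orientations only and with probes present in all replicates were chosen after the data were seen, as was every test of the oxidative phosphorylation list between times. Counts at 18 h and 192 h stayed at 0 in all 37 alternatives each, with 96 to 314 and 11 to 193 probes at an unadjusted p under 0.05. At 72 h limma called 3 probes without background correction and with median centring, 2 with scale normalization, scan 2 alone, scan 3 alone or total RNA only, and 1 with RNA type as a covariate or with all 28 arrays. Leaving out 1 replicate in turn gave 0 to 299 probes at 72 h, 0 to 156 for the mean and 0 to 138 between times. The highest 3 came without 72 h replicate 4, where the lone replicate 3, which holds array 447, is assumed to vary like the others. Scale normalization gave 1 probe between times. Replicate numbers were to count as pairs only if every pair sharing a number correlated above 0.1: 5 of 8 did, from -0.122 to 0.326, so they were not, though 6 of 10 replicates correlated best with their own number. Residuals of the fit correlated at -0.653 and -0.615 for numbers 1 and 2. Only these numbers carry a dye value in the fit, and the dye term itself sets their residuals against each other. Those residuals therefore do not bear on pairing. A fixed replicate block in place of the dye term, 2 changes at once, gave 3 probes at 72 h, 1 for the mean and 0 elsewhere, and a random replicate block with the dye term gave 0 throughout. Planned list tests called 2 without background correction (oxidative phosphorylation at 18 h and 192 h), 1 with all 28 arrays (the same list at 192 h) and 1 with probes in all replicates (ion channels at 192 h). The oxidative phosphorylation difference kept its sign in all 23 alternatives and lost its call in 12: -0.079 with the dimmest 50% left out, -0.0885 without the dye term, -0.064 with total RNA, -0.093 with polyA RNA, -0.067 with probes in all replicates, and 7 of the 11 fits without 1 replicate. Those 11 fits ranged from -0.097 to -0.069. The largest differences kept the call: -0.154 with all 28 arrays, -0.131 with median centring and -0.118 without background correction. The first of these includes the 7 arrays whose annotation was not borne out. Named genes were picked from these same data by p or moderated t, some also by one sign in every replicate. That pick favours kept signs, so their number is no support for these genes. Of 426 values of named genes, 417 kept their sign and 18 moved by more than 1 SD. The cause of these moves was not tested. polyA RNA alone gave no 72 h or mean value, leaving out 72 h replicates 1 and 2 was not run since none of their arrays was in use, and background subtraction equals the values used. On the 21 arrays used for named genes, median signal over background ran from 0.654 to 3.18 in Cy3 and 0.745 to 4.04 in Cy5, which limits what weakly expressed genes can show.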

Other observations

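The genes here were picked after their values were seen, mostly from the lists too small for a list test, and none passed limma's test over all genes. Irf9, a transcription factor of interferon signalling, had a log2 ratio of -0.69 at 192 h (SE 0.27, n = 4), above 0 in 1 replicate, while the other 2 measured genes of that list, Isg15 and Ifi27, had -0.28 (SE 0.14, n = 4) and 0.02 (SE 0.21, n = 3). Abcb1a, an efflux transporter of the blood-brain barrier, had -0.35 at 18 h (SE 0.14, n = 4), and the other measured endothelial gene, Eng, had -0.03. The 4 measured microglial genes at 192 h were P2ry12 at 0.08, Itgam at -0.09, C1qb at 0.03 and Laptm5 at -0.14. Th, the rate-limiting enzyme of dopamine synthesis, belongs to a tested list and had 0.26 at 192 h (SE 0.12, n = 4), 0.09 at 18 h and -0.38 at 72 h (n = 2).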
